A study of Mus musculus with 2 samples.

How the data were processed

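Lens RNA of Msx2 conditional knockout (CKO) and of wild type at postnatal day 1 was profiled on 1 array each. Per the labels' protocols, total RNA was checked for integrity, purified, amplified and labelled with Cy3 by a low-input one-colour kit. Per the file headers, the arrays were of Agilent mouse design 014868, were read in 1 channel, and were extracted with Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, with probe positions in mm9. The submitters' processing notes name Agilent Feature Extraction 10.7. Both arrays carry the same scan identifier in their headers, so slide and scan did not differ between the genotypes. The labels give each array replicate number 1.

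The scanner files that the authors deposited give the intensity of each spot on a linear scale. The processed intensity used here had already been corrected for background and for spatial trends within the array by Feature Extraction, per the file headers, and had not been normalized between arrays. The authors also deposited a table of log2 values, with a median of 4.87 for each array. Its sorted columns differ by at most 0.0004, as after quantile normalization between the arrays, and its columns correlate with the log2 scanner signal of the same array at r = 0.9996 and r = 0.9998 across probes. Its difference between the arrays correlates with that of the scanner signal at r = 0.987 and runs in the same direction. How the table was scaled and shifted is not given in the sources used here, and it served only as an alternative.

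From the scanner files, log2 of the processed signal was taken and the 75th percentile of the non-control spots of each array was subtracted (203 intensity units in CKO and 201 in wild type). Control spots were left out, as were spots marked as population outliers (169 and 251) or non-uniform (0 and 1), and the spots of a probe were averaged. A probe was called well above background when more than 50% of its spots carried the scanner software's mark for this. A gene was measured when a probe was well above background and unsaturated on both arrays, which held for 21010 probes of 14221 genes, and the gene took the value of its brightest probe. In 4847 genes with more than 1 measured probe, the SD of the log2 difference between probes of a gene was 0.36. A gene with probes well above background on 1 array only was given an at-least fold, from its brightest probe there against the higher of the lowest signal well above background on the other array and the probe's own signal there.

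Gene symbols were updated with a RefSeq gene table of assembly GRCm38.p6, used for names only. It matched 27667 probes by accession, 5589 by symbol and 471 by an older symbol, and 7446 kept the name in the file. Coordinates are those of the files.

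With 1 array per genotype no test across animals exists. Differences are log2 CKO minus log2 wild type, counted when at least 2-fold. The 39 gene lists (lens genes, pathways, processes and markers of cell types that a dissected lens could carry), the settings, the alternatives and the rule for named genes were fixed before the data were examined. Those named are Msx2, the 12 genes with the largest difference in each direction, the 4 with the largest at-least fold in each direction, and the 4 measured members of each list with the largest difference, some of which are not reported here. Genes known only by a clone, an accession or a provisional symbol were counted and not named, which left 11798 genes. A list's shift is the median log2 difference of its measured genes minus the median of all measured genes, and its percentile was taken among 10000 random lists matched in size and in level over 20 bins. Lists with fewer than 5 measured genes got no percentile. The alternatives were normexp background correction (offset 50) of the mean signal and local background, median scaling, quantile normalization, intensity-dependent centring, the deposited log2 table, other filters on dim probes, the mean of all probes of a gene, other fold thresholds, the mean of a list and lists without shared genes.

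The procedure was tested on simulated data for this comparison with 14221 genes, of which 200 were changed 4-fold. It found 199 of them (99.5%), and 180 unchanged genes also passed 2-fold. Of 1000 random lists 57 (5.7%) fell in the outer 5% of positions, and all 50 shifted lists were found. The simulated differences were drawn independently, with a smaller SD than that of the measured genes (0.60). These figures therefore do not give the error rates for the real genes, or for lists whose members vary together. Normexp was run with limma 3.58.1 in R 4.3.3. The other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.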

Results

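Gene expression was measured in the lenses of mice at postnatal day 1. The CKO sample came from a conditional knockout of Msx2, a homeobox transcription factor, made with Le-Cre, a transgene that expresses Cre recombinase in the lens lineage. It was compared with a wild-type sample, and the labels do not say whether the wild type carried Le-Cre. Each genotype had 1 one-colour oligonucleotide array, so no difference below has a replicate check, no p-value is given, and how many animals went into each RNA is not given in the sources used here. Each array held 45018 spots, of which 43379 were not controls and represented 41174 probes. In the CKO sample 22702 probes (55.1%) were well above background and in wild type 22326 (54.2%), with median local backgrounds of 38 and 37.5 intensity units and no saturated spots. A total of 14221 genes were measured, that is, well above background on both arrays, and their log2 levels correlated across genes with r = 0.97. The number of arrays limits the precision. Within the arrays, 122 measured probes printed as repeated spots gave an SD of 0.27 for the log2 difference of a single spot, 0.10 for the brighter and 0.36 for the dimmer of them.

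Msx2 itself was examined first, as a check of the genotype labels. In wild type its probe gave a signal of 371 ± 15.9 intensity units (SD over 10 spots of the same array, range 335 to 394), and all 10 spots were well above background. In the CKO sample the signal was 4.62 ± 1.77 (10 spots, range 3.34 to 9.37), and 0 of the 10 spots were well above background. Msx2 was therefore at least 22.6-fold lower in the CKO lens, the bound set by the lowest signal that counted as well above background on that array. With normexp background correction, which adds an offset to every spot, the log2 difference was -2.60, smaller in size than this bound (4.50 on the log2 scale). The probe, A_51_P388661, lies on chromosome 13 from 53563333 to 53563392 (mm9, per the file), with the sequence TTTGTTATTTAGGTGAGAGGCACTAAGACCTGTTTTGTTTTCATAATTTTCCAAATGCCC. Whether this stretch lies within the deleted part of the gene is not given in the sources used here.

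**Figure D1:**
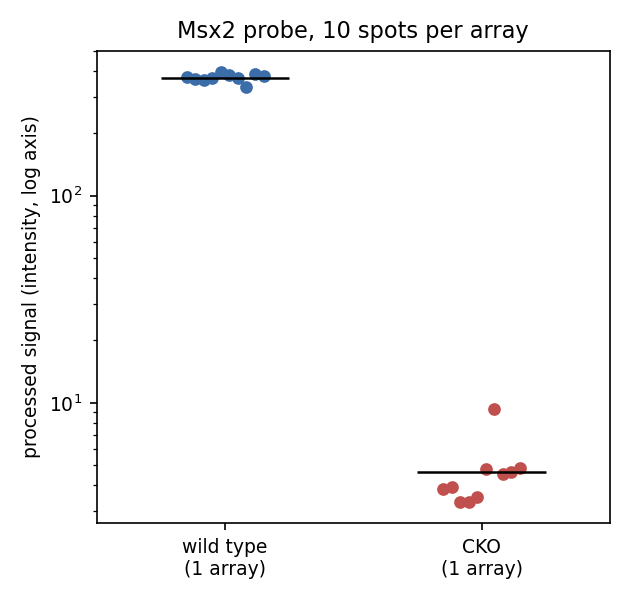
Signal of the 10 Msx2 spots on each array (log scale, intensity units). Every wild-type spot lay between 335 and 394 and every CKO spot between 3.34 and 9.37, and none of the CKO spots was well above background.

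The comparison of CKO with wild type asks which genes differ in the lens when Msx2 is deleted. The most marked difference was in genes of macrophages. Ctss, a lysosomal protease of antigen-presenting cells, was 42.3-fold higher in the CKO lens, Trem2, a receptor of macrophages and microglia, 23.5-fold, and its signalling adaptor Tyrobp 16.6-fold. Their log2 differences were 5.40, 4.55 and 4.05, and with normexp background correction 4.12, 2.55 and 2.83. In wild type Trem2 lay near the lowest level that counted as well above background. Genes of blood vessels and of the cell cycle were also higher, whereas genes of lens fibre cells, the elongated cells that make up most of the lens, were lower as a group. Crystallins, the main structural proteins of the lens, differed little where they were measured on both arrays.

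Altogether 584 genes were at least 2-fold higher and 566 at least 2-fold lower in the CKO lens, so 50.8% of these genes were higher. With each array scaled to its median in place of its 75th percentile the counts were 470 and 844, or 35.8% higher, and with normexp background correction they were 233 and 218. Apart from the macrophage genes, the genes with the largest excess in the CKO lens included Lypd2 (30.7-fold), the stress-induced cytokine Gdf15 (28.7-fold), the fibrillar collagen gene Col3a1 (28.5-fold), the monocyte chemokine gene Ccl7 (24.1-fold) and the interleukin gene Il4 (17.1-fold). Col3a1 was near the lower limit in wild type, and its log2 difference of 4.83 was 2.91 with normexp. The metallothionein genes Mt2 and Mt1, which encode metal-binding proteins, were 14.3-fold and 14.2-fold higher, although another measured probe of Mt1 differed by only 0.18 on the log2 scale. Trf, the gene of the iron carrier transferrin, was 12.5-fold higher and the complement gene C3 11.1-fold.

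In the other direction, Clic5, a chloride intracellular channel gene, was 11.2-fold lower in the CKO lens, and both of its measured probes were lower (log2 differences of -3.48 and -3.01). Tbc1d30 was 7.96-fold lower, Slx1b, which encodes a subunit of a structure-specific endonuclease, 7.15-fold, and Usp45, a deubiquitinase gene, 5.80-fold, and each of these also had a pair of measured probes that were lower. Single probes gave Krt1, a keratin gene of differentiated epidermis, as 9.36-fold lower, Abca13 as 8.53-fold, the vasopressin gene Avp as 7.48-fold and Lingo4 as 6.41-fold. Rubcn, a regulator of autophagy, was 5.79-fold lower, the kinase gene Wnk2 5.62-fold, Klhl30 5.55-fold and Card6 5.45-fold. In the CKO lens Krt1, Abca13 and Klhl30 lay near the lowest level that counted as well above background. Their log2 differences of -3.23, -3.09 and -2.47 were -1.54, -1.57 and -1.05 with normexp. The probe of Ctss lies on chromosome 3 from 95360162 to 95360221, that of Lypd2 on chromosome 15 from 74562684 to 74562743, that of Col3a1 on chromosome 1 from 45405589 to 45405648, and that of Clic5 on chromosome 17 from 44416979 to 44417038 (all mm9). The single measured probe of Wnk2 lies on chromosome 13 from 49138116 to 49138175 (mm9), within 10 Mb of the Msx2 probe.

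A further 1070 genes were well above background in the CKO lens only, 372 of them by at least 2-fold over the floor of the other array, and 861 in wild type only, 217 of them by at least 2-fold. With normexp background correction these at-least counts were 87 and 20. Retnla, a secreted protein gene of macrophages and epithelia, was at least 1962-fold higher in the CKO lens (chromosome 16 from 48844447 to 48844506, mm9). Dcn, the gene of the matrix proteoglycan decorin, was at least 344-fold higher, Rnase2a, a member of a family of closely related ribonuclease genes, at least 129-fold, and Cdkn1a, the cell cycle inhibitor p21, at least 79.8-fold. Among genes well above background in wild type only, the neutral amino acid transporter gene Slc6a15 was at least 9.58-fold lower in the CKO lens, Usp17la, one of a cluster of near-identical genes and so uncertain, at least 8.28-fold, Akap4 at least 8.18-fold and Gcsam at least 7.76-fold.

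**Figure D2:**
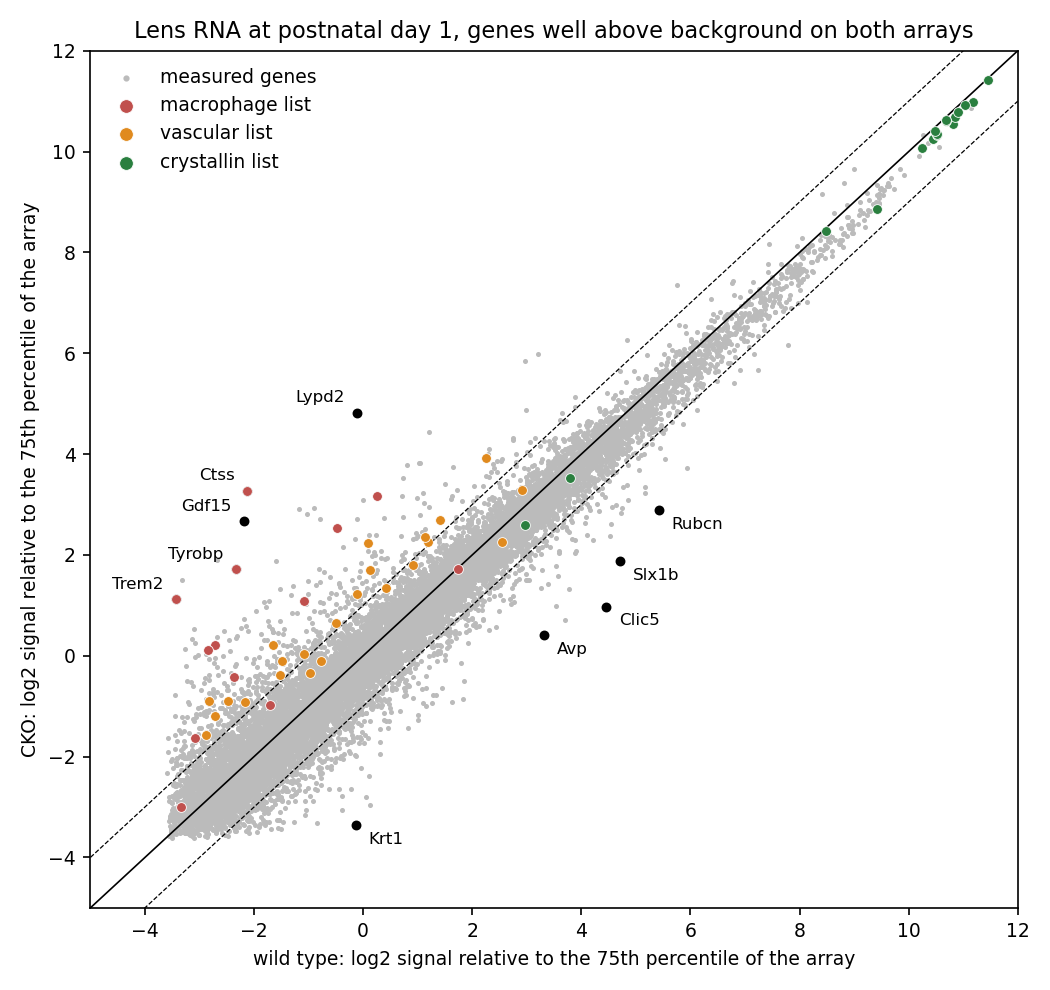
Log2 signal relative to the 75th percentile of the array in wild type (horizontal) and CKO (vertical) for the 14221 measured genes, each point 1 gene, with lines of equality and of 2-fold differences. Macrophage genes (red) and vascular genes (orange) lie mostly above the upper line, with 10 of 13 and 17 of 23 genes at least 2-fold higher, and the crystallins (green) lie close to equality.

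Gene lists were compared by the median log2 difference of their measured members, given as a shift relative to the median of all measured genes, which was itself -0.12. Each shift was set beside 10000 random lists of the same size and expression level. Of 37 lists with at least 5 measured genes, 20 lay among the highest 2.5% of random lists and 1 among the lowest, where 1.85 would be expected by chance if the lists were independent. The high lists were macrophages, vascular cells, ciliary body and iris, pigment cells, corneal stroma, both cell cycle phases, cell cycle inhibitors, interferon response, inflammasome, epithelial-mesenchymal transition, the BMP, FGF, Wnt and Notch pathways, immediate early genes, unfolded protein response, heat shock, autophagy and ion channels. These positions describe the 2 arrays and not the genotypes.

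Fibre cell genes formed the list that lay among the lowest 2.5%, with a shift of -0.45 over 25 measured genes (random lists from -0.27 to 0.05). Of these genes 4 were at least 2-fold lower, 0 were at least 2-fold higher, and 5 lay above the median of all genes. The fibre shift was -0.23 with quantile normalization, -0.26 with intensity-dependent centring and -0.22 with the deposited value table. Lgsn, which encodes the lens protein lengsin, was 4.64-fold lower, the apoptosis inhibitor gene Birc7 2.66-fold, the fatty acid binding protein gene Fabp5 2.35-fold, and Dnase2b, the nuclease that degrades DNA in maturing fibre cells, 2.13-fold. None of the 17 measured members of the crystallin list differed by 2-fold, and their shift of -0.07 was within the random range of -0.31 to 0.03. Most of them were among the brightest measured genes, with Crygd at a level percentile of 99.99. Whether differences are compressed at such signals was not tested. Another 2 members, Cryl1 and Crym, were well above background in the CKO lens only, with at-least folds of 1.72 and 37.3. Like Cryz and Cryzl1, they are not alpha, beta or gamma crystallin genes. The shift of the crystallins had the opposite sign with quantile normalization (0.05), with the deposited value table (0.05) and with intensity-dependent centring (0.19, among the highest 2.5%). Among them Crygn was 1.46-fold lower, Cryzl1 1.30-fold, Cryz 1.21-fold and Crybb3 1.21-fold, and single probes cannot tell the closely similar gamma crystallin genes Cryga to Crygf apart with certainty.

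Genes of the lens epithelium, the dividing cell layer at the front of the lens, shifted by 0.09 over 23 measured genes, which was within the random range. Of these, 2 were at least 2-fold higher, the water channel gene Aqp1 (3.74-fold) and the mitotic kinase gene Cdk1 (2.63-fold). Clu, the gene of the chaperone clusterin, was 2.34-fold lower, and Sfrp1, a secreted Wnt antagonist, was 1.84-fold lower. Lens transcription factors shifted by 0.06 over 25 genes, again within the random range, but were among the highest 2.5% with no filter on detection (0.13). In that list E2f1 was 2.04-fold higher and Hey1 1.75-fold higher, while Maf and Prox1, regulators of fibre cell differentiation, were 1.96-fold and 1.84-fold lower. Ion channels and transporters of the lens shifted by 0.23 over 25 genes, among the highest 2.5%, with 1 gene at least 2-fold higher, the cation channel gene Trpv4 (2.02-fold). That shift was within the random range with quantile normalization (0.19), with intensity-dependent centring (0.19), with the deposited value table (0.19) and with the mean of the list (0.12).

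Macrophage and microglia genes had the largest shift of the lists, 3.03 (8.15-fold) over 13 measured genes, against random lists from -0.27 to 0.38. All 13 lay above the median of all genes, 10 were at least 2-fold higher and 0 at least 2-fold lower. Besides Ctss, Trem2 and Tyrobp, the chemokine gene Pf4 was 8.11-fold higher. Another 14 genes of the list were well above background in the CKO lens only and 1 in wild type only, and with these set at their bound the shift was 3.05. With normexp background correction the shift was 1.61. Genes of neutrophils and lymphocytes were within the random range, with a shift of 0.39 over 6 measured genes, among them Cd79a, a B cell receptor component, at 2.79-fold higher and the myeloperoxidase gene Mpo at 1.89-fold lower. This shift was among the highest 2.5% of random lists with the mean of all probes of a gene (0.46) and without shared genes (0.55).

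Vascular genes shifted by 1.36 (2.57-fold) over 23 measured genes, with 17 at least 2-fold higher and 0 at least 2-fold lower. Vwf, the gene of von Willebrand factor, was 4.41-fold higher, the endothelial receptor genes Tie1 and Eng 3.84-fold and 3.66-fold, and the tight junction gene Cldn5 3.19-fold. Red blood cell genes shifted by -0.11 over 10 genes, within the random range, with Slc4a1, the anion exchanger of red cells, 2.09-fold lower, Tmod1 1.68-fold lower and Car2 4.01-fold higher.

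Genes of other eye tissues differed from one another. The ciliary body and iris list shifted by 1.24 over 13 genes, with 7 at least 2-fold higher and 1 lower, and included Zic1 (5.01-fold higher), Col9a2 (4.23-fold), Aldh1a3, a retinoic acid synthesis gene (4.03-fold), and the carbonic anhydrase gene Car2 (4.01-fold). The shift of this list was 0.71 with normexp and 0.81 with no filter on detection. Genes of pigment cells shifted by 0.73 over 7 genes, 3 of them at least 2-fold higher and 0 lower, with the melanin synthesis gene Dct 10.6-fold higher, Trpm1 2.99-fold higher, Pmel 2.83-fold higher and Mitf 1.87-fold lower, and their shift was within the random range with normexp (0.24), 1.30 with genes seen on 1 array at their bound and 1.69 with probes well above background on at least 1 array. Corneal stroma and ocular mesenchyme shifted by 0.57 over 11 genes, of which 5 were at least 2-fold higher and 1 lower, and a further 10 genes were well above background in the CKO lens only. Mgp was 7.93-fold higher in that list, the collagen gene Col1a2 7.08-fold and the matrix protein gene Postn 6.98-fold. This shift was within the random range without genes shared with other lists (0.11) and with only probes above the median probe level (0.29), and with genes seen on 1 array at their bound it was 1.76.

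Retina and photoreceptor genes were within the random range (shift 0.08 over 7 genes), with Elavl4 4.75-fold lower and Rbpms 2.90-fold higher, and the sign of that shift was negative with quantile normalization (-0.06). So were genes of the surface epithelium of cornea, conjunctiva and skin (-0.28 over 9 genes), with Krt18 4.52-fold higher and Krt17 2.24-fold lower beside Krt1, but these were among the lowest 2.5% with quantile normalization (-0.39) and with the deposited value table (-0.40). Skeletal muscle genes shifted by -0.03 over 16 genes, 3 of them at least 2-fold higher and 1 lower, with Cox6a2 3.46-fold, Acta1 2.59-fold and Actc1 2.05-fold higher and Actn2 2.67-fold lower. Astrocyte and optic nerve glia genes shifted by 0.03 over 9 genes, 3 of them at least 2-fold higher and 2 lower, with Gfap 3.21-fold lower, Glul, glutamine synthetase, 2.66-fold higher, Fabp7 2.5-fold higher and Aqp4 2.18-fold higher, and both of these lists were within the random range. With no filter on detection the muscle shift was 0.21, among the highest 2.5%. Lacrimal and Harderian gland genes had only 2 measured members, Aqp5 at 1.80-fold lower and Ltf at 1.08-fold higher, and no percentile was computed for them.

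**Figure D3:**
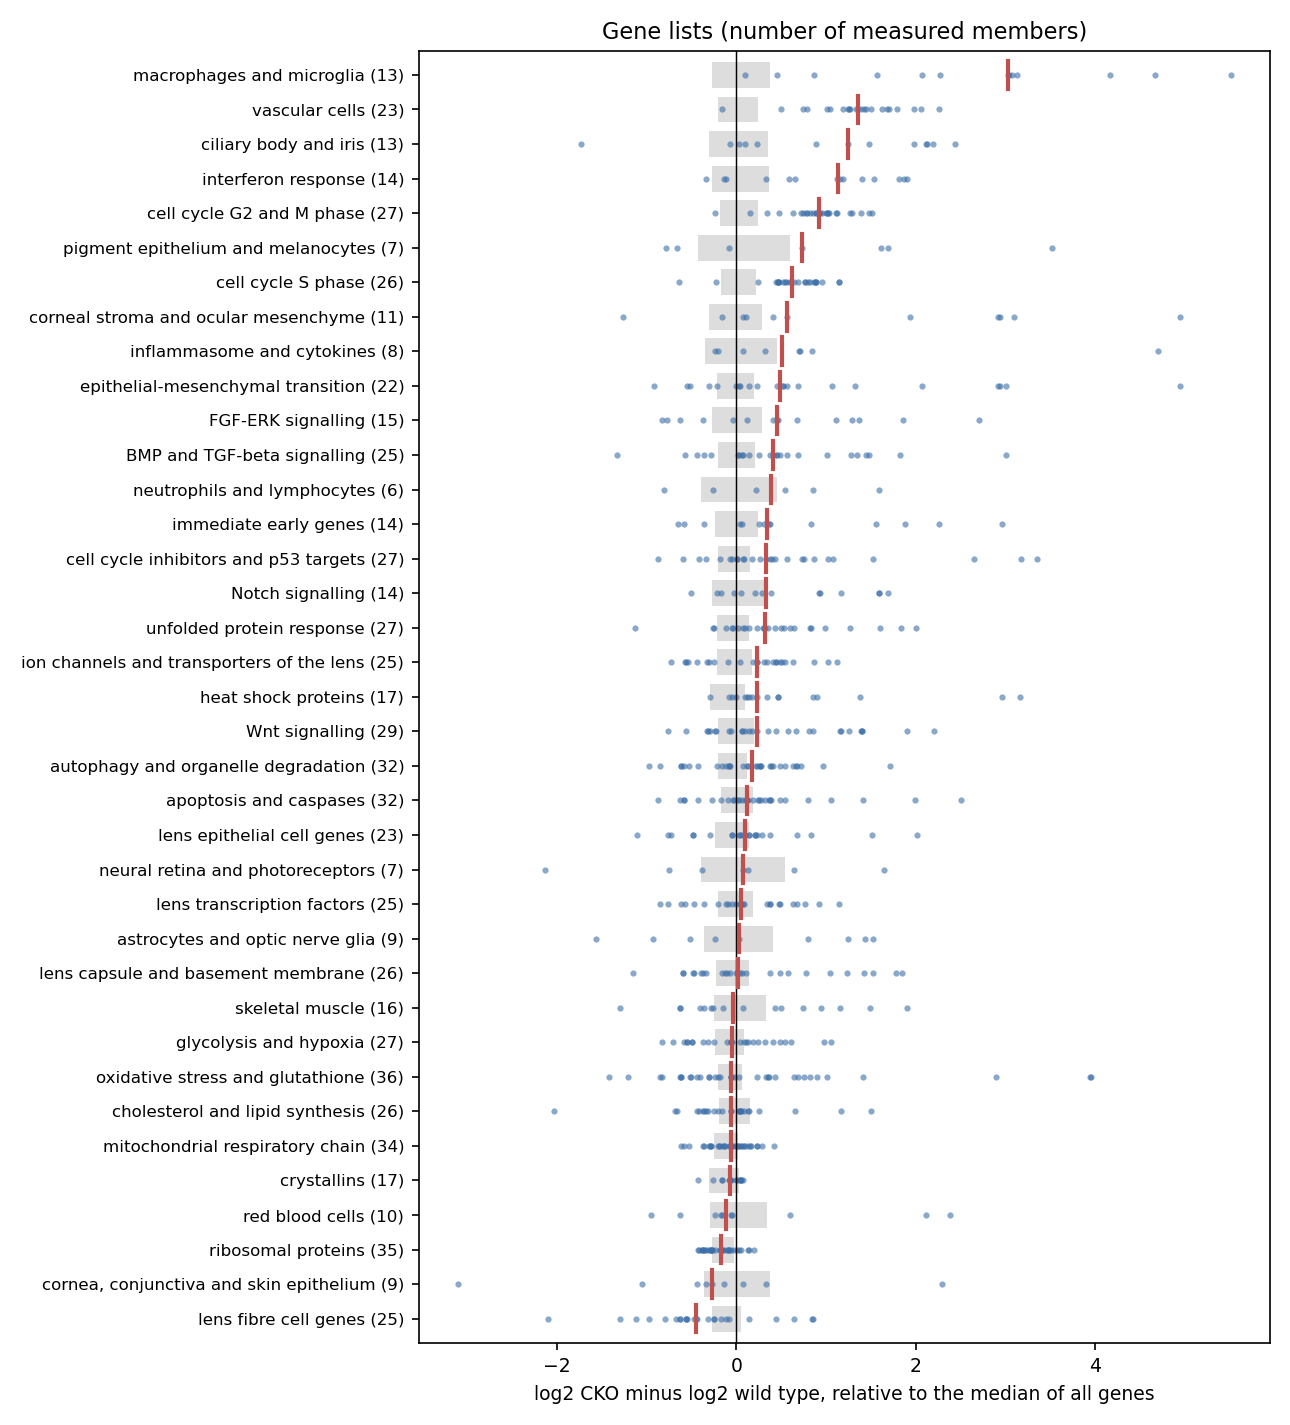
Gene lists with at least 5 measured genes, on a log2 scale of CKO minus wild type relative to the median of all measured genes, with points for single genes, a red line for the list median and a grey bar for the central 95% of random lists of the same size and level. The macrophage list lies farthest to the right at 3.03, followed by vascular cells at 1.36, and the lens fibre list lies to the left of its random range at -0.45.

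Cell cycle genes were higher as a group. The G2 and M phase list shifted by 0.93 (1.90-fold) over 27 measured genes, of which 26 lay above the median of all genes, 6 were at least 2-fold higher and 0 at least 2-fold lower. With normexp the shift was 0.55. Cdk1 was 2.63-fold higher, the ubiquitin-conjugating enzyme gene Ube2c 2.57-fold, Cdca3 2.41-fold and the centromere histone gene Cenpa 2.26-fold. The S phase list shifted by 0.63 over 26 genes, of which 24 lay above the median of all genes and 2 were at least 2-fold higher, with Chaf1b at 2.04-fold, E2f1 at 2.04-fold, the primase gene Prim1 at 1.79-fold and Gins1 at 1.71-fold. In the same comparison the macrophage and vascular lists shifted by 3.03 and 1.36.

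Inhibitors of the cell cycle and targets of p53 shifted by 0.34 over 27 genes, with 4 at least 2-fold higher, 0 lower and another 4 well above background in the CKO lens only. Phlda3 was 9.40-fold higher, the inhibitor gene Cdkn2b 8.37-fold, Trp53inp1 5.78-fold and Bbc3, which encodes the pro-apoptotic protein PUMA, 2.64-fold. The macrophage and vascular lists shifted by 3.03 and 1.36 on the same arrays. Apoptosis and caspase genes were within the random range (0.12 over 32 genes), although the death receptor gene Tnfrsf1a was 5.25-fold higher and Ripk3 3.68-fold. The apoptosis list was among the highest 2.5% with no filter on detection (0.13) and with the mean of the list (0.22).

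Genes of the interferon response shifted by 1.14 (2.20-fold) over 14 measured genes, 8 of them at least 2-fold higher and 0 lower. Another 6 were well above background in the CKO lens only, with at-least folds of 1.13 to 3.55. The regulator gene Irf7 was well above background in wild type only, and was at least 4.63-fold lower in the CKO lens. The interferon shift was 0.60 both with normexp and with no filter on detection, and 0.80 with genes seen on 1 array at their bound. Psmb8, an immunoproteasome subunit gene, was 3.46-fold higher, B2m, the light chain of major histocompatibility class I molecules, 3.38-fold, Mx2 3.24-fold and Gbp2 2.68-fold. Inflammasome and cytokine genes shifted by 0.51 over 8 measured genes, and 10 more were well above background in the CKO lens only. That shift was within the random range with normexp (0.22) and with quantile normalization (0.39), and was 0.88 with genes seen on 1 array at their bound. Apart from Ccl7 the largest differences there were under 2-fold, in Nfkbia (1.66-fold higher), Myd88 (1.51-fold) and Tlr2 (1.5-fold). Both lists contain genes that macrophages express, and the macrophage list shifted by 3.03 in the same comparison.

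Among signalling pathways, BMP and TGF-beta genes, the pathway in which Msx2 is a known target, shifted by 0.41 over 25 genes, with 6 at least 2-fold higher and 1 lower. Tgfbi, induced by TGF-beta, was 7.40-fold higher, the receptor gene Tgfbr2 3.28-fold and Msx1, a close relative of Msx2, 2.57-fold, while the signal transducer gene Smad1 was 2.72-fold lower. With normexp the BMP and TGF-beta shift was 0.26. FGF and ERK genes shifted by 0.46 over 15 genes, of which 4 were at least 2-fold higher, namely the transcription factor genes Etv4 (6.02-fold) and Etv5 (2.38-fold) and the feedback inhibitor genes Dusp6 (3.34-fold) and Spred2 (2.25-fold). With no filter on detection the FGF and ERK shift was 0.19. Notch genes shifted by 0.33 over 14 genes, 4 of them at least 2-fold higher and 0 lower, with Hes5 2.98-fold, Heyl 2.78-fold, Mfng 2.78-fold and Jag2 2.07-fold higher, and with only probes above the median probe level the shift of 0.24 was within the random range. The Notch shift was 0.22 with normexp, 0.60 with the mean of all probes of a gene and 0.66 without shared genes. Wnt genes shifted by 0.23 over 29 genes, 8 of them at least 2-fold higher and 0 lower, with Dkk2 4.25-fold, Tcf7 3.45-fold, Wnt5a 2.43-fold and Lgr5 2.43-fold higher. The Wnt shift was -0.040 with only probes above the median probe level, and was within the random range with normexp (0.12) and with intensity-dependent centring (0.20). Vascular and mesenchymal cells also express members of these lists, and the vascular list shifted by 1.36.

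The epithelial-mesenchymal transition list shifted by 0.49 over 22 genes, with 6 at least 2-fold higher and 1 lower, led by Col3a1, Tgfbi, Col1a2 and Postn. Of the list's members, 12 stand on other lists as well, and corneal stroma and ocular mesenchyme shifted by 0.57. With only probes above the median probe level the transition list was within the random range (0.17). Lens capsule and basement membrane genes were within the random range (0.02 over 26 genes), although the vascular basement membrane genes Col15a1 and Lama4 were 3.32-fold and 3.18-fold higher, Col18a1 2.65-fold and Nid2 2.48-fold, and the mean of the list (0.21) was among the highest 2.5%.

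Stress response genes were higher in several lists, beside shifts of 3.03 for macrophages, 1.36 for vascular cells and 0.57 for corneal stroma in the same comparison. Heat shock protein genes shifted by 0.23 over 17 genes, 3 of them at least 2-fold higher and 0 lower, with Hspa1a, a copy of a near-identical gene pair, 8.24-fold higher, Hspb8 7.19-fold, Bag3 2.40-fold and Hspa4l 1.72-fold. The heat shock shift was 0.20 with no filter on detection, 0.39 with quantile normalization and 0.60 with the mean of the list. Genes of the unfolded protein response shifted by 0.32 over 27 genes, 4 of them at least 2-fold higher and 1 lower, with Ddit4 3.70-fold, Ddit3, which encodes the transcription factor CHOP, 3.30-fold and Sdf2l1 2.80-fold higher, and with Ppp1r15a 2.37-fold lower. Immediate early genes shifted by 0.34 over 14 genes, 4 of them at least 2-fold higher and 0 lower, with Egr1 7.19-fold, Junb 4.42-fold, Klf4 3.39-fold and Ier2 2.72-fold higher, but were within the random range with quantile normalization (0.25) and with only probes above the median probe level (0.19). The immediate early shift was 0.83 with genes seen on 1 array at their bound, 0.83 with probes well above background on at least 1 array and 0.63 with the mean of the list. Autophagy and organelle degradation genes shifted by 0.18 over 32 genes, 1 of them at least 2-fold higher and 1 lower, with the cargo receptor gene Sqstm1 3.02-fold higher and Map1lc3a 1.81-fold higher, and the mean of that list (0.084) was within the random range. Oxidative stress and glutathione genes were within the random range (-0.06 over 36 genes) with members far apart, since Gsta4 was 6.85-fold higher and the catalase gene Cat 2.90-fold lower beside the metallothioneins. Their sign was positive with quantile normalization (0.08) and with the mean of the list (0.22), which lay among the highest 2.5%.

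Metabolic lists were within the random range. Glycolysis and hypoxia genes shifted by -0.05 over 27 genes, with none at least 2-fold higher or lower, and the respiratory chain list by -0.06 over 34 genes, also with none. Ribosomal protein genes shifted by -0.17 over 35 genes, within the random range of -0.27 to -0.03 for genes of their level. The signs of these 3 shifts were positive with quantile normalization (0.09, 0.08 and 0.03). Cholesterol and lipid synthesis genes shifted by -0.06 over 26 genes, and in that list Dhcr7, the last enzyme of cholesterol synthesis, was 4.44-fold lower and Insig1 2.61-fold higher.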

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

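The counts relative to the median of all genes and the list shifts with genes seen on 1 array at their bound were chosen after the results were seen. No paired analysis was possible because each genotype has 1 array and the only replicate number they share is 1, and no replicate could be left out. Of the alternative values for the main results, 468 kept their side of the threshold or moved within 1.5 times, 16 list shifts moved into the random range, 8 moved out of it, 15 values moved further and 4 reversed. The 468 include values that could not change, namely list shifts with median scaling and all values with saturated probes kept. Signal over background limits the sizes. The Msx2 probe was at background in CKO, so its difference is only a bound, and with normexp the difference was -2.60. With the same correction the counts of genes at least 2-fold higher and lower were 233 and 218, and those of genes seen on 1 array only were 87 for CKO and 20 for wild type. Genes at least 2-fold higher and lower numbered 1276 and 1043 with probes well above background on at least 1 array, 2026 and 1753 with no filter, 184 and 257 with only probes above the median level of measured probes (8159 genes), 1331 and 2090 at 1.5-fold, and 211 and 107 at 3-fold. Relative to the median of all genes they numbered 720 and 384, within 1.5 times of the main counts. Median scaling moved the median of all genes by -0.12 and intensity-dependent centring by 0.10. Keeping saturated probes changed nothing, since no spot was saturated.

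The fibre cell list stayed among the lowest 2.5% in every alternative run, with shifts from -0.53 with no filter to -0.22 in the value table, and the macrophage, vascular, S phase and G2 and M phase lists stayed among the highest 2.5%. Shifts that moved into the random range were, with normexp, Wnt 0.12, inflammasome 0.22 and pigment cells 0.24. With quantile normalization they were inflammasome 0.39, immediate early genes 0.25 and ion channels 0.19, and ion channels also with centring (0.19), with the value table (0.19) and with the mean of the list (0.12). Wnt was 0.20 with centring, and with only probes above the median probe level Notch was 0.24, epithelial-mesenchymal transition 0.17, immediate early genes 0.19 and corneal stroma 0.29, while Wnt reversed to -0.040. Autophagy was 0.084 with the mean of the list in place of its median, and corneal stroma was 0.11 without shared genes. Shifts that moved out of the random range were lens transcription factors 0.13 and apoptosis 0.13 with no filter, apoptosis 0.22 and lens capsule 0.21 with the mean of the list, surface epithelium -0.39 with quantile normalization and -0.40 in the value table, and neutrophils and lymphocytes 0.46 with the mean of all probes of a gene and 0.55 without shared genes. Crystallins reversed to 0.19 with centring, oxidative stress to 0.22 with the mean of the list and skeletal muscle to 0.21 with no filter. The cause of these changes was not tested. Of the alternative values for single named genes, 1403 moved by less than the SD between spots, 138 moved further and 0 reversed.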

Other observations

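The tests on macrophage, vascular and cell cycle genes, including the activation lists, were chosen after the results were seen, and those on strain sequence, on the segment around Msx2 and on dim probes before.

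A list of genes that macrophages express when activated by interleukin-4, called alternative activation, was drawn up after the results were seen. Of its 16 genes, 9 (56.2%, exact 95% interval 29.9 to 80.2) were at least 2-fold higher or well above background in the CKO lens only. Besides Retnla, Ccl24 was at least 66.3-fold higher, Chil3 at least 66.2-fold, the arginase gene Arg1 at least 16.9-fold, Tgm2 at least 8.59-fold, the mannose receptor gene Mrc1 at least 6.08-fold and Clec10a at least 5.30-fold. Folr2 was 5.39-fold higher and the interleukin-4 receptor gene Il4ra 2.01-fold. Of 16 genes of classical activation, 4 (25%, 7.3 to 52.4) met the same criterion, and genes such as Nos2, Il1b, Il6 and Tnf were not well above background on either array. Those 4 met it by being well above background in the CKO lens only, with at-least folds of 1.16 to 1.87. The intervals overlap and the genes were chosen with the results in view, so whether the CKO lens may hold macrophages in a state of alternative rather than classical activation stays open. Both activation lists, with Retnla among their members, were drawn up after the values were seen. Some of their members, such as Mrc1, Il1b, Il6 and Tnf, also stand on lists fixed before.

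Y-linked genes were well above background in both samples, with a log2 difference of -0.43 for Ddx3y, -0.09 for Eif2s3y, -0.06 for Kdm5d and -0.06 for Zfy1, and Xist was not well above background on either array. These 4 genes are the measured members of the list of X inactivation and Y chromosome genes.

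Macrophage and vascular genes were higher together, with shifts of 3.03 and 1.36, and 14 of 29 and 23 of 28 list members were well above background in the wild-type lens. A smaller share of lens RNA would raise all other cell types alike. The vascular median exceeded that of red blood cells by 1.47 (95% range over resampled members 0.33 to 1.80), and Hba-a1 differed by -0.16 from a log2 level of 3.26 in wild type. These values argue against a smaller lens share as the whole cause only if lens cells do not express the red cell genes. That was not tested, and Tmod1 of the red cell list also stands on the lens fibre list. More of an adhering tissue, vessels with their macrophages, remains a candidate explanation, since the macrophage median exceeded the vascular one by 1.66 (0.15 to 1.88) but vascular genes that lens cells also express could have diluted the second shift. Several eye tissues left at dissection also stay open, since ciliary body and iris genes shifted by 1.24 and retina genes by 0.08. An effect of the Msx2 deletion, or of the Le-Cre transgene, cannot be separated from these with 1 array per genotype.

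G2 and M phase genes were higher in the CKO lens while fibre cell genes were lower, which could come from a larger share of lens epithelium. That explanation stays open. The G2 and M phase median exceeded that of lens epithelial genes by 0.84 (95% range over resampled members 0.64 to 1.00). Epithelial list members that fibre cells also express could have diluted the epithelial shift, so this difference cannot decide. Of the 25 epithelial list members, 14 stand on other lists and 23 were well above background in wild type. Dividing macrophages or vascular cells, and more division within the lens epithelium in the absence of Msx2, stay open and were not tested.

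The genes at least 2-fold higher or lower may in part reflect strain differences, as the strains are not given in the sources used here. Only 117 of the 584 genes that were higher and 146 of the 566 that were lower had another measured probe. For these genes, sequence differences under single probes are argued against as the main cause. Other probes of the same gene had the same sign and at least 50% of the size in 86 of the 117 (73.5%, Wilson 95% interval 64.9 to 80.7) and in 86 of the 146 (58.9%, 50.8 to 66.6). For genes with 1 measured probe this explanation stays open. A segment of another strain around Msx2 stays open, since 14 of 125 genes within 10 Mb of its probe differed at least 2-fold (11.2%, exact 95% interval 6.3 to 18.1) against 8.1% of genes on other chromosomes. Noise of dim probes also stays open for the genes that were lower, which made up 2.91% of genes above the median level and 5.05% of those below it, a ratio of 0.58 (95% interval 0.49 to 0.68). For the genes that were higher this ratio was not computed, and noise stays open there too. With only probes above the median probe level, 184 of 8159 genes were higher and 257 lower, against 584 and 566 of 14221.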
